A study of Mus musculus with 8 samples.

How the data were processed

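The series holds RNA from uterine stromal cells of ovariectomized mice of a strain given as C57BL/6-ICR, with 4 groups of 2 libraries: mice with the floxed Atg7 gene intact (control) or deleted by Amhr2-driven Cre, each given oil or estradiol. Nothing in the labels says whether the libraries came from separate animals, so p-values measure only the spread between these samples, and the counting intervals and read floors given for genes with few reads cover counting error alone. How the stromal cells were separated, the estradiol dose and the time after injection are not given in the labels. Per the labels, 500 ng of total RNA per library, extracted with Trizol, went into a QuantSeq library kit, which reads the 3′ ends of polyadenylated transcripts, so a gene's reads do not grow with its length and no length correction was made.

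The authors deposited a file of counts per library, which hold raw read counts per gene symbol with no normalization. The unit was settled from the values, which are whole numbers whose totals differ between libraries. The submitters' processing notes name Bowtie2, edgeR and the mouse genome build mm10, without versions or roles. The read counter and gene annotation are not given in the sources used here. Counts of genes with near-identical copies depend on how reads with several matches were handled: Ccl21a, Ccl21b and Gm1987 had 454, 452 and 451 reads in control estradiol library 1. Each file listed 23282 lines for 23238 symbols. For the 35 symbols that occurred more than once, on 79 lines, the line with the highest total was kept. The lines left out held 0.0973% of all counts (0.0815% to 0.110% per library). Gene coordinates came from GENCODE M21, on the same build, in which 22197 of the symbols had a matching name.

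Genes were kept with the filterByExpr function of edgeR (minimum count 10, minimum total count 15), which left 13347 genes holding 99.9% of counts, and 4998 symbols were at 0 in every library. Scaling used the trimmed mean of M-values (TMM), with factors from 0.918 to 1.03. Quasi-likelihood tests in edgeR 4.0.16 (R 4.3.3) were run on 1 model with a mean for each of the 4 groups. The contrasts were estradiol against oil within each genotype, deletion against control within each treatment, the averages of each pair, and the interaction, which is the difference between the 2 estradiol effects. The model had 4 residual degrees of freedom and 5.08 prior degrees of freedom, and the biological coefficient of variation was 21.8%. P-values were adjusted over all tested genes by the method of Benjamini and Hochberg at 0.05, and counts adjusted over a list alone applied the same method to the members of that list. Standard errors came from the fitted fold change and its test statistic. Levels are given as CPM, the counts of a gene scaled to a common library size with the TMM factors.

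Fixed before the data were examined were the contrasts, the rule for naming genes, the alternatives named as planned in the closing part, and 37 gene lists. The lists were immediate early genes, heat shock genes, steroid receptors, estrogen targets of the uterus, epithelial estrogen targets, progesterone and decidual stroma genes, cell cycle genes, ribosome biogenesis genes, vascular permeability genes, extracellular matrix genes, autophagy core genes, autophagy receptor genes, lysosome genes, NRF2 targets, unfolded protein response genes, inflammatory mediators, interferon response genes, cholesterol synthesis genes, glycolysis and hypoxia genes, oxidative phosphorylation genes, mitochondrially encoded genes and paracrine growth factors. Further lists were the neighbours of Atg7 and of Amhr2, and markers of fibroblasts, epithelium, smooth muscle, pericytes, endothelium, macrophages, granulocytes, lymphocytes and NK cells, mast cells, erythroid cells, mesothelium, adipocytes and Schwann cells. They hold 732 genes, of which 655 were tested, and 39 tested genes stand in more than 1 list. Lists with at least 3 tested members, 33 in all, were tested with camera in limma 3.58.1 with a preset correlation of 0.01 between members, adjusted over the lists of a contrast. The preset correlation takes members of a list as nearly independent, so each list was also tested with the correlation estimated from the residuals and with fry.

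The genes named are Atg7 and Amhr2, and for each pairwise contrast and the interaction the 10 largest rises and 10 largest falls with an adjusted p below 0.05, a mean of at least 10 CPM and no overlap between the libraries of the groups. Predicted genes, mitochondrial transcripts and ribosomal pseudogenes were passed over, and where fewer than 3 genes passed, the 5 smallest p-values were taken. Up to 4 members per list and contrast with the smallest adjusted p were added, and for markers of other cell types the 3 members with the highest mean CPM. Genes given for the average deletion effect, and genes given because they passed when adjusted over their list alone, were chosen after their values were seen. Folds against a group with no reads are lower bounds against a floor of 3 counts over the group. Ratios against 1 to 3 reads carry a 95% counting interval. A count of 3 corresponds to 0.432 to 0.550 CPM in a library.

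The libraries held between 5458390 and 6951080 counts, and distances from the estimate to either end of its 95% interval had a median of 0.657 (log2) for deletion in oil, 0.653 after estradiol and 0.464 for the average deletion effect. The precursor of ribosomal RNA, Rn45s, took 4.22% to 6.49% of the counts of a library. The procedure was tested on simulated data with these library sizes and this dispersion, in which 100 genes were changed 2-fold and 100 others 4-fold. For deletion in oil, 21 of the 2-fold and 82 of the 4-fold changes were called, with 5 false calls. For the estradiol effect the counts were 12, 72 and 10, for the interaction 1, 38 and 1, and for the average deletion effect 60, 92 and 11. A list of 30 simulated genes shifted by 0.5 on the log2 scale was called by camera (adjusted p = 7.91e-11), and 0 of the other lists were. The simulated genes were drawn independently, without differences between libraries that many genes share, so the shares called may not hold for the real libraries. For the same reason, false calls of lists with correlated members were not examined.

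Alternatives were other scalings (RLE, upper quartile, totals only), no filter or a stricter filter (5 CPM in 2 libraries), DESeq2 1.42.0, limma-voom, a fit of the 2 compared groups alone, a 2-fold threshold, thinning to equal depth, the replicate number as a block and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9.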

Results

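The libraries measured RNA from stromal cells of the uterus, the connective tissue cells that lie under its epithelium. The mice had been ovariectomized, which removes the main source of ovarian hormones, and had received either oil or estradiol (E2), the main estrogen of the ovary. In the control mice the autophagy gene Atg7 was flanked by recombination sites and intact. In the other mice the Cre recombinase was expressed from Amhr2, a gene active in the mesenchyme of the reproductive tract, so that Atg7 was deleted in the uterine mesenchyme. No group is described as carrying Cre with Atg7 intact, so effects of Cre itself cannot be told apart from those of the deletion. The comparison set out in the series asks which genes differ in stroma with Atg7 deleted, and the oil and estradiol groups allow that question to be asked at rest and after the hormone. Each of the 4 groups had 2 libraries. Dose and time of the estradiol injection are not given in the labels.

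Library totals ran from 5458390 to 6951080 counts, and 15527 to 15963 gene symbols had at least 1 read per library. Of 23238 symbols, 13347 had enough reads to be tested. Estradiol set the libraries apart along the first principal component, which carried 66.9% of the variance: the 4 oil libraries lay between -66.9 and -45.3 and the 4 estradiol libraries between 49.9 and 60.0. The second component carried 12.3% and separated library 1 from library 2 in oil, at 43.4 and -34.0 in control stroma and at 13.8 and -32.3 in Atg7-deleted stroma. Correlation across genes between the replicates of a group (genes are not independent replicates) was 0.950 in control oil, 0.975 in control estradiol, 0.969 in deleted oil and 0.978 in deleted estradiol. In control oil, 14.9% of genes lay more than 2-fold apart between the 2 libraries, against 5.16% to 7.38% in the other groups. Control oil library 1 resembled deleted oil library 1 (r = 0.976 across genes) more closely than control oil library 2.

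**Figure D1:**
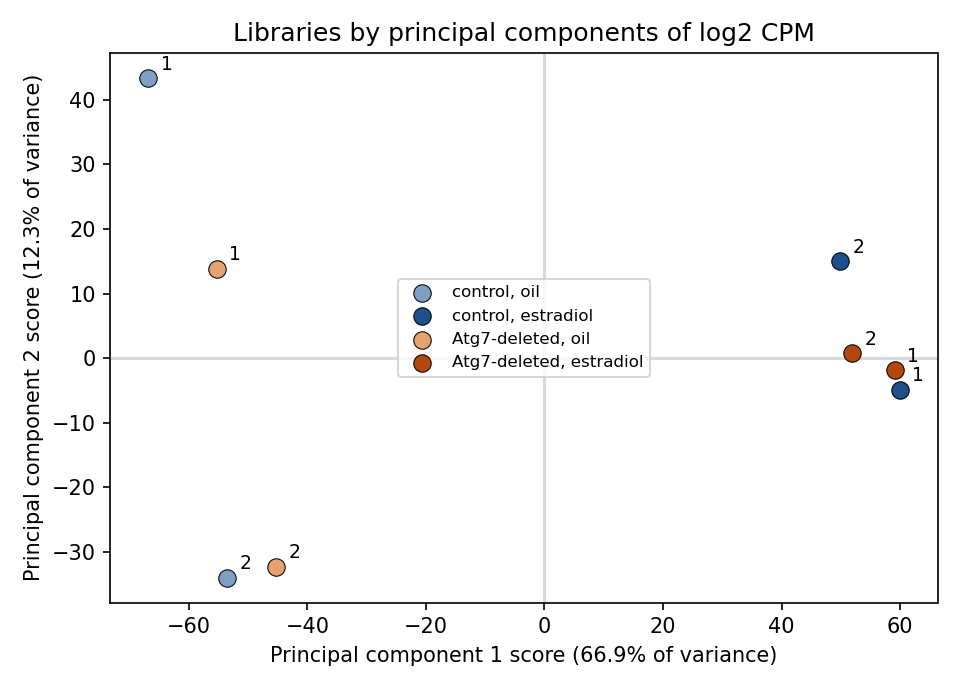
Each point is a library, placed by its scores (unitless) on the first and second principal components of the log2 CPM of the tested genes, with its replicate number beside it. Oil libraries lie left of 0 and estradiol libraries right of 0 on the first axis, and the control oil libraries lie farthest apart on the second, at 43.4 and -34.0.

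Atg7 itself (chromosome 6, 114643097 to 114860614, plus strand, mm10 coordinates from GENCODE M21), which encodes the E1-like enzyme that starts conjugation of LC3 and ATG12, had few reads in every library. Counts were 22 and 32 in control oil, 20 and 23 in control estradiol, 21 and 33 in deleted oil, and 23 and 22 in deleted estradiol. Mean Atg7 levels were 4.57 ± 1.55 CPM (mean ± SD, n = 2 libraries per group, here and for all CPM values below) in control oil and 4.26 ± 1.33 in deleted oil, a log2 fold change of -0.09 ± 0.42 (SE, here and for all fold changes below). After estradiol they were 3.16 ± 0.524 and 3.85 ± 0.410, a log2 fold change of 0.28 ± 0.44. Reads of this library type come from the 3′ ends of transcripts, so a deletion of internal exons that leaves the 3′ end transcribed is not seen in these counts. Amhr2 (chromosome 15, 102445367 to 102454633, plus strand), the gene whose promoter drives the recombinase, had 20 and 13 reads in control oil, 2 and 8 in control estradiol, 2 and 11 in deleted oil, and 3 and 0 in deleted estradiol. Its log2 fold change with deletion was -1.40 ± 0.93 in oil. After estradiol the ratio of control to deleted reads was 2.86 (95% counting interval 0.737 to 16.2). Neither Atg7 nor Amhr2 passed the test in any comparison of 2 groups. The 19 tested neighbours of Atg7 had a median log2 fold change with deletion of -0.09 in oil (adjusted p = 0.315) and -0.02 after estradiol (adjusted p = 0.921, above 0 when scaled by library totals alone, at 0.01). For the 22 tested neighbours of Amhr2 the medians were 0.04 (adjusted p = 0.149) and 0.02 (adjusted p = 0.948).

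Estradiol changed the stroma of control mice broadly, raising most genes of the extracellular matrix and cell cycle lists and lowering many early response and heat shock genes. Col1a1 (chromosome 11, 94936224 to 94953042, plus strand), a chain of type I collagen, rose from 44.1 ± 6.42 to 1542 ± 490 CPM, a log2 fold change of 5.13 ± 0.31. Cdk1 (chromosome 10, 69335146 to 69352938, minus strand), the kinase that drives entry into mitosis, rose from 7.96 ± 1.24 to 126 ± 16.3 CPM. Igf1 (chromosome 10, 87858265 to 87937042, plus strand), a growth factor that acts from stroma on epithelium, rose from 76.6 ± 21.3 to 682 ± 85.7 CPM. Wif1 (chromosome 10, 121033960 to 121100650, plus strand), a secreted inhibitor of Wnt proteins, fell from 112 ± 26.7 to 1.43 ± 0.938 CPM. In all, 3978 of the 13347 tested genes (29.8%) changed with estradiol (edgeR, adjusted p below 0.05), 2107 up and 1871 down, of which 1396 and 1191 moved at least 2-fold. The count was 1505 without control estradiol library 1 and 1928 without control estradiol library 2.

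Among the genes with the largest changes, several were close to absent in oil. Tmprss11a, a membrane serine protease, had no read in control oil and 283 reads after estradiol, at least 82.8-fold higher (floor of 3 reads over the group). Reads of Crabp1, a retinoic acid binding protein, were 221-fold higher (95% counting interval 60.8 to 1827), and those of Crtac1, a cartilage matrix protein, 182-fold (50.2 to 1512). Hsd11b2 (chromosome 8, 105518755 to 105523988, plus strand), the enzyme that inactivates glucocorticoids, rose from 2.70 ± 0.691 to 129 ± 44.1 CPM. Lcn2 (chromosome 2, 32384633 to 32388252, minus strand), a secreted iron carrier, rose from 6.72 ± 2.99 to 217 ± 47.7 CPM. Scgb3a1, a secretoglobin, rose by 5.13 ± 0.53 on the log2 scale, by 7.11 without control oil library 1 and by 4.35 without control oil library 2. Among the genes that fell furthest were Gkn3 (chromosome 6, 87383256 to 87388935, minus strand), a gastrokine, at -6.01 ± 0.66, the secreted ribonuclease Rnase1 at -4.99 ± 0.33, the tight junction gene Cldn1 at -4.80 ± 0.60 and the glutathione transferase Gstm7 at -4.61 ± 0.38. Gkn3 stood at -7.28 without control estradiol library 2 and at -5.29 without control estradiol library 1, and Cldn1 at -5.86 without control estradiol library 2 and at -4.15 without control oil library 1, with calls kept in all 8 fits without 1 library. Reads of Aldh1a3, which makes retinoic acid, were 204-fold lower (36.2 to 8105).

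Genes of proliferation, matrix, sterol synthesis and respiration rose together in control stroma. In the same comparison the mean log2 CPM of fibroblast markers went from 6.03 to 7.71 and that of epithelium markers from 6.86 to 5.42. A change in the mix of cells was not separated from regulation within cells. Of 37 cell cycle genes, 34 rose, none fell and 3 did not pass (35 rose when adjusted over the list alone), with a median log2 fold change of 2.41. Besides Cdk1, the mitotic cyclin Ccna2 rose by 3.60 ± 0.26, the transcription factor E2f1 by 3.21 ± 0.23 and the topoisomerase Top2a by 2.99 ± 0.22 on the log2 scale. For this list the camera adjusted p was 5.21e-28 with the preset correlation, and the adjusted p was 0.123 with an estimated correlation. Of 41 extracellular matrix genes, 25 rose and 3 fell (27 and 3 adjusted over the list alone, median 1.27, adjusted p = 1.33e-13, and adjusted p = 0.283 with an estimated correlation). Col6a2 rose by 4.23 ± 0.28, Col6a3 by 3.27 ± 0.27 and the matrix glycoprotein Sparc by 2.23 ± 0.22. Of 23 cholesterol synthesis genes, 19 rose and none fell (20 adjusted over the list alone, median 1.67, adjusted p = 1.6e-11, and adjusted p = 0.132 with an estimated correlation). Sqle, a rate-controlling step of sterol synthesis, rose by 3.09 ± 0.25 and Fdps, an enzyme of the isoprenoid steps, by 2.59 ± 0.30. Of 25 oxidative phosphorylation genes, 23 rose and none fell (23 adjusted over the list alone, median 0.95, adjusted p = 8.81e-10, and adjusted p = 0.283 with an estimated correlation), among them Ndufa4 at 1.69 ± 0.23 and Sdhc at 1.35 ± 0.19. Of 16 estrogen targets known from epithelium, 12 rose and none fell (13 up and 1 down adjusted over the list alone, median 2.70, adjusted p = 6.88e-09, and adjusted p = 0.283 with an estimated correlation). These included Padi1, a protein-citrullinating enzyme, at 2.75 ± 0.32 and Cfb, a complement factor, at 3.46 ± 0.46.

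Unfolded protein response genes moved in both directions. Of 26 members, 11 rose, 5 fell and 10 did not pass (15 and 5 adjusted over the list alone, median 0.65, adjusted p = 0.0215, and adjusted p = 0.823 with an estimated correlation). Pdia4 rose by 1.81 ± 0.20 and Creld2 by 2.02 ± 0.29, whereas the stress transcription factor Ddit3 fell by 1.76 ± 0.23. The call ended without control oil library 2 (adjusted p = 0.349) and without control estradiol library 1 (adjusted p = 0.0558).

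Early response and heat shock genes fell. Of 30 immediate early genes, 16 fell, none rose and 14 did not pass (19 down and 1 up adjusted over the list alone, median -0.998, adjusted p = 2.4e-08, and adjusted p = 0.123 with an estimated correlation). The transcription factors Jund and Klf2 fell by 1.38 ± 0.19 and 1.33 ± 0.17, and the antiproliferative gene Btg2 fell by 1.25 ± 0.17. Of 14 heat shock genes, 8 fell and none rose (8 adjusted over the list alone, median -0.91, adjusted p = 0.00387, and adjusted p = 0.823 with an estimated correlation). Hspb1 fell by 1.39 ± 0.20 and Hspa1b by 1.52 ± 0.23, the latter with the limit that reads of Hspa1a and Hspa1b cannot be told apart with certainty. When control oil library 1 was left out, the heat shock median was -0.51 and the call ended (adjusted p = 0.131). Markers of epithelium fell in the same comparison, by a median of -1.42.

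Of 27 autophagy core genes, 2 rose, 2 fell and 23 did not pass (0 and 1 adjusted over the list alone, median -0.19, adjusted p = 0.381). Map1lc3b (chromosome 8, 121590361 to 121598760, plus strand), which encodes the LC3B protein that Atg7 helps to attach to membranes, fell from 291 ± 30.3 to 160 ± 12.0 CPM, and this call ended without control estradiol library 1 (adjusted p = 0.0659). Of 13 autophagy receptor genes, 6 fell and none rose (6 adjusted over the list alone, median -0.30, adjusted p = 0.0532). The receptor p62, encoded by Sqstm1 (chromosome 11, 50199366 to 50210827, minus strand), fell from 897 ± 12.6 to 390 ± 9.26 CPM, and Calcoco1 fell by 1.69 ± 0.29 on the log2 scale. The receptor list passed without deleted estradiol library 1 (adjusted p = 0.0481) and without deleted estradiol library 2 (adjusted p = 0.0476). Of 33 lysosome genes, 4 rose and 3 fell (4 and 3 adjusted over the list alone, median 0.13, adjusted p = 0.999). Mitf, a transcription factor of the lysosomal gene family, fell by 2.80 ± 0.20, the protease Ctsf fell by 2.17 ± 0.31 and the glucuronidase Gusb rose by 1.65 ± 0.21. The list of mitochondrially encoded genes could not be measured, since no member was tested.

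The remaining lists had members moving in both directions or few calls. Of 31 estrogen targets of the uterus, 8 rose and 7 fell (8 and 7 adjusted over the list alone, median -0.18, adjusted p = 0.996), with Wnt4 at -1.41 ± 0.23. Of 24 progesterone and decidual stroma genes, 6 rose and 5 fell (6 and 6 adjusted over the list alone, median 0.14, adjusted p = 0.842). Of 5 steroid receptors, 2 rose and none fell (2 adjusted over the list alone, median 0.23, adjusted p = 0.644). The progesterone receptor Pgr rose from 197 ± 4.58 to 361 ± 31.7 CPM, a call that ended without control estradiol library 1 (adjusted p = 0.0702), and the estrogen receptor Esr1 stood at 0.23 ± 0.17 (adjusted p = 0.325). Of 36 paracrine growth factors, 7 rose and 10 fell (9 and 12 adjusted over the list alone, median -0.31, adjusted p = 0.842), with Wnt5a at 2.38 ± 0.28. Of 26 vascular permeability genes, 7 rose and 6 fell (7 and 9 adjusted over the list alone, median 0.01, below 0 with 2 other scalings, adjusted p = 0.999). The fenestral diaphragm gene Plvap rose by 2.54 ± 0.25, and Vegfa, the main vascular permeability factor, fell by 2.09 ± 0.26. Of 27 NRF2 targets, 8 rose and 4 fell (10 and 4 adjusted over the list alone, median -0.02, above 0 with library totals, adjusted p = 0.934), with Me1 at 1.75 ± 0.25, Hmox1 at -1.75 ± 0.23 and Gstm1 at -1.59 ± 0.16. Of 28 ribosome biogenesis genes, 7 rose and 2 fell (8 and 2 adjusted over the list alone, median 0.47, adjusted p = 0.137, and 0.0300 without control oil library 1). Of 23 glycolysis and hypoxia genes, 6 rose and 7 fell (7 and 7 adjusted over the list alone, adjusted p = 0.842), with a median of 0.27 but a mean of -0.17 and a downward test. Of 25 inflammatory mediators, 4 rose and 3 fell (4 and 3 adjusted over the list alone, median 0.06, adjusted p = 0.842). Of 26 interferon response genes, 4 rose and 1 fell (1 and 1 adjusted over the list alone, median 0.18, adjusted p = 0.842).

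**Figure D2:**
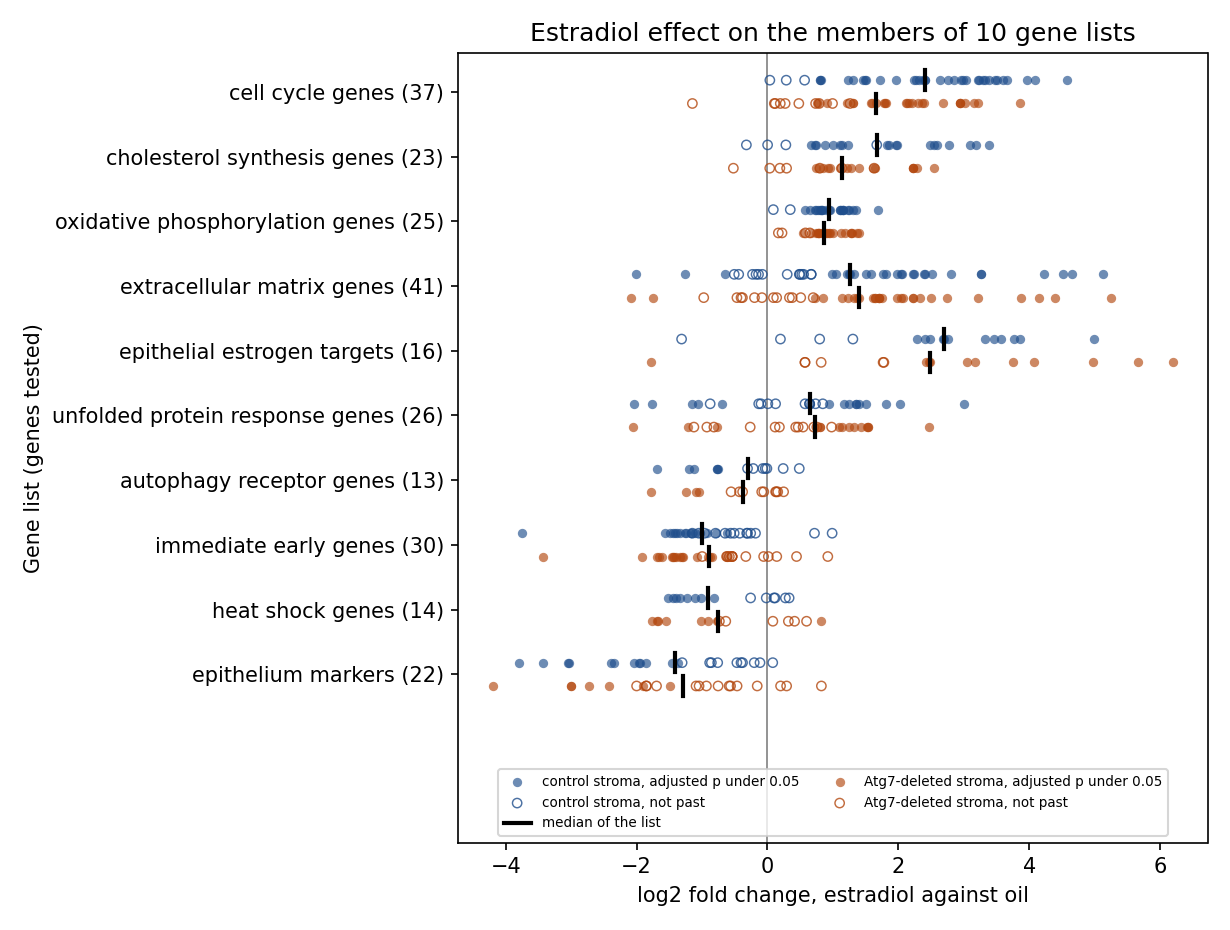
Log2 fold change of estradiol against oil for each tested member of 10 gene lists, in control stroma (blue) and Atg7-deleted stroma (orange), filled where the adjusted p was below 0.05, with black bars at the list medians. The cell cycle median was 2.41 in control and 1.66 in Atg7-deleted stroma, and the epithelium medians were -1.42 and -1.29.

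Markers of other cell types were present and moved with estradiol. Of 14 fibroblast markers, 10 rose and 2 fell (12 and 2 adjusted over the list alone, median 1.32, adjusted p = 1.68e-07, and adjusted p = 0.283 with an estimated correlation), led by collagen genes, with the proteoglycan Lum at 2.23 ± 0.23. Of 22 epithelium markers, 12 fell and none rose (12 adjusted over the list alone, median -1.42, adjusted p = 3.65e-05, and adjusted p = 0.823 with an estimated correlation). The claudin Cldn4 stood at 4369 ± 2892 CPM in oil and 526 ± 314 after estradiol, and the keratin Krt18 at 2131 ± 1581 and 198 ± 92.6. Their log2 fold changes were -3.05 and -3.43, and -2.12 and -2.33 without control oil library 1, while Cldn4 stood at -3.84 without control estradiol library 2 and Krt18 at -4.08 without control oil library 2. Their calls ended without control estradiol library 1 (adjusted p = 0.0663 and 0.0580). Cdh16 fell by 3.80 ± 0.54. Without control oil library 1 the epithelium median was -0.81 (adjusted p = 0.0101). Of 15 smooth muscle markers, 6 rose and 1 fell (6 and 1 adjusted over the list alone, median 0.88, adjusted p = 0.0392, and adjusted p = 0.917 with an estimated correlation). Actg2, smooth muscle actin, rose by 3.37 ± 0.58, by 4.85 without control oil library 2 and by 2.67 without control oil library 1. That list had a median of 0.37 without control oil library 1 (adjusted p = 0.545) and 1.58 without control oil library 2.

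Among vascular and blood cell markers, 3 of 20 endothelium markers rose and 5 fell (4 and 9 adjusted over the list alone, median -0.35, adjusted p = 0.44, and 0.0252 without control oil library 1). Of 8 pericyte markers, 1 rose (1 adjusted over the list alone, median 0.38, adjusted p = 0.552). For 7 erythroid markers, 6 rose (6 adjusted over the list alone, median 1.01, adjusted p = 0.0602). That list passed without control oil library 2 (adjusted p = 0.0396) and without control estradiol library 2 (adjusted p = 3.98e-04). Of 15 macrophage markers, 3 rose and 1 fell (3 and 1 adjusted over the list alone, median 0.47, adjusted p = 0.502). Of 7 granulocyte markers, 1 rose (1 adjusted over the list alone, median 0.86, adjusted p = 0.842). Of 3 lymphocyte and NK markers, 1 fell (1 adjusted over the list alone, median -0.94, adjusted p = 0.487). None of 5 mast cell markers changed (edgeR, 0 adjusted over the list alone, median -0.21, adjusted p = 0.842). Mesothelium, adipocyte and Schwann cell lists had 2 tested genes each and no list test. Both mesothelium markers fell (median -1.52), 1 adipocyte marker rose (median 1.07, and 2 adjusted over the list alone), and no Schwann cell marker passed (median -0.04, above 0 with library totals).

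**Figure D3:**
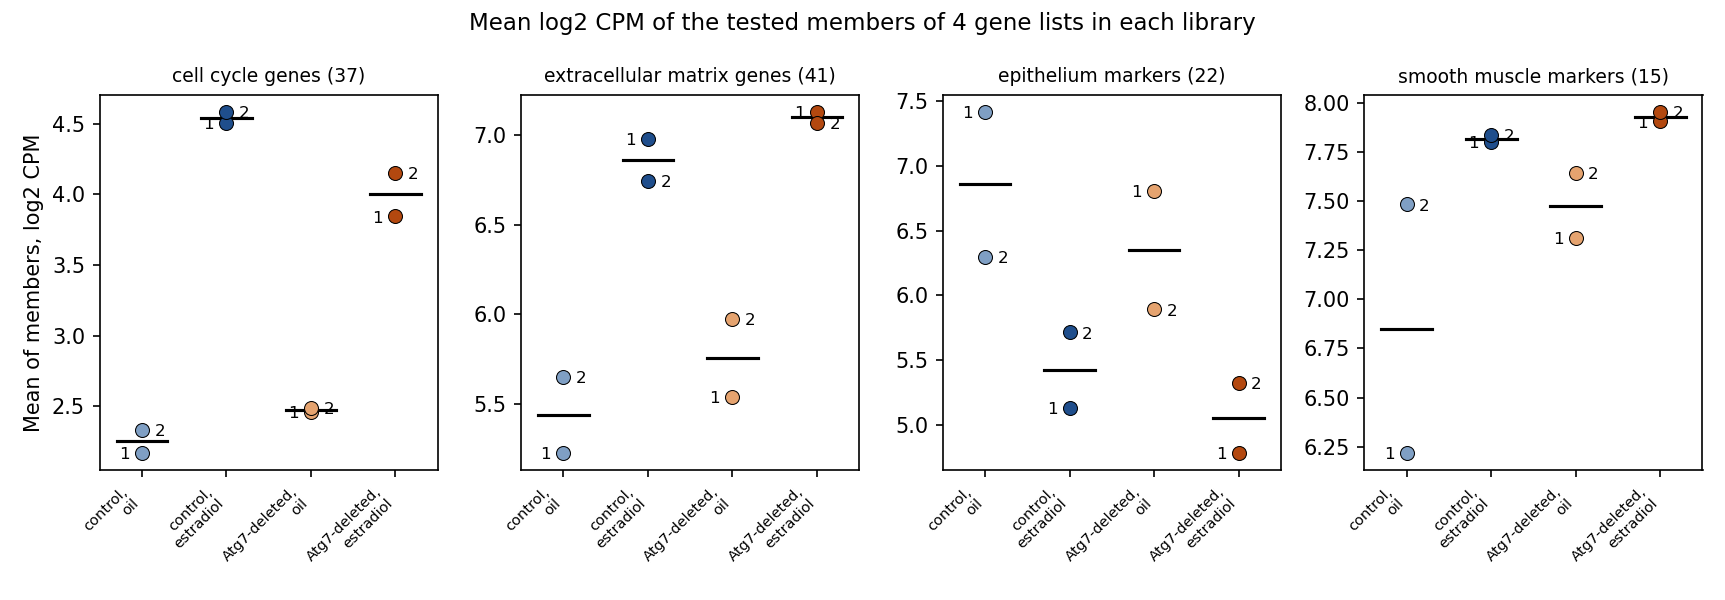
Mean log2 CPM of the tested members of 4 gene lists in each library (points, with replicate numbers) and group means (lines). Cell cycle means lay at 4.50 and 4.58 in control estradiol and at 3.84 and 4.15 in deleted estradiol, and epithelium means in control oil lay at 7.42 and 6.30.

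In Atg7-deleted stroma, estradiol moved the same leading genes. Col1a1 rose from 52.0 ± 13.2 to 1982 ± 76.2 CPM and Igf1 from 86.5 ± 20.7 to 800 ± 12.0 CPM. Lcn2 rose by 5.66 ± 0.35, Hsd11b2 by 5.34 ± 0.40 (5.95 without deleted oil library 2) and Scgb3a1 by 5.93 ± 0.60 on the log2 scale. Wif1 fell from 99.9 ± 21.6 to 1.90 ± 0.625 CPM and the carboxylesterase Ces1d fell by 4.43 ± 0.43. In this genotype 3242 genes (24.3%) changed, 1746 up and 1496 down, of which 1141 and 988 moved at least 2-fold. The count was 740 and 1065 without deleted estradiol libraries 1 and 2, and 1289 and 1634 without deleted oil libraries 1 and 2. Both genotypes shared 1459 genes that rose and 1240 that fell, where 276 and 210 would be shared if calls were independent, and no gene was called in opposite directions. Of the 4521 genes called in either genotype, 4488 (99.3%) had the same sign in both. Across all tested genes the estradiol effects correlated at r = 0.867 (Spearman 0.868). A larger count in control stroma is not a tested difference, which is the interaction given further on.

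By group, the estradiol response of Atg7-deleted stroma followed the same lists. Of 37 cell cycle genes, 27 rose and none fell (29 adjusted over the list alone, median 1.66, adjusted p = 4.57e-15, and adjusted p = 0.24 with an estimated correlation). Cdk1 rose from 15.5 ± 1.42 to 81.6 ± 19.4 CPM and Ccna2 by 3.02 ± 0.27 on the log2 scale. Matrix genes (27 up, 2 down of 41, median 1.39, adjusted p = 6.05e-15), fibroblast markers (10 up, 1 down of 14, median 1.18, adjusted p = 1.07e-07), cholesterol synthesis genes (16 up of 23, median 1.14, adjusted p = 5.5e-08) and oxidative phosphorylation genes (21 up of 25, median 0.86, adjusted p = 7.04e-10) rose. Epithelial estrogen targets rose as well (10 up, 1 down of 16, median 2.48, adjusted p = 3.9e-09). With an estimated correlation these adjusted p-values were 0.262, 0.262, 0.24, 0.24 and 0.268 in that order. Adjusted over the list alone, 27, 10, 18, 23 and 12 members of these lists rose. Unfolded protein response genes had 11 up and 3 down of 26 (14 and 4 adjusted over the list alone, median 0.73, adjusted p = 0.0101, and adjusted p = 0.811 with an estimated correlation), and 0.0906 without deleted oil library 2.

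Falling groups were also shared. Of 30 immediate early genes, 17 fell (18 adjusted over the list alone, median -0.89, adjusted p = 1.38e-09, and adjusted p = 0.12 with an estimated correlation), with Klf2 at -1.66 ± 0.17. Of 14 heat shock genes, 7 fell and 1 rose (8 and 1 adjusted over the list alone, median -0.75, adjusted p = 0.00298, and adjusted p = 0.811 with an estimated correlation), with Hspb1 at -1.68 ± 0.20. Of 22 epithelium markers, 7 fell (11 adjusted over the list alone, median -1.29, adjusted p = 1.22e-04, and adjusted p = 0.811 with an estimated correlation), and the median was -0.62 without deleted oil library 1. Autophagy receptor genes had 4 down of 13 (4 adjusted over the list alone, median -0.38, adjusted p = 0.0549), and passed without deleted oil library 1 (adjusted p = 0.0378) or deleted estradiol library 2 (adjusted p = 0.0462). Sqstm1 fell by 1.09 ± 0.17, a call that ended without deleted estradiol library 1 (adjusted p = 0.0561). Smooth muscle markers, called in control stroma, had 5 up and 1 down of 15 here (6 and 3 adjusted over the list alone, median 0.40, adjusted p = 0.425). Macrophage markers had a median of 0.72 (1 up and 1 down of 15, adjusted p = 0.155, and 0.0085 without deleted estradiol library 2). Autophagy core genes had 1 up and 2 down of 27 (1 and 1 adjusted over the list alone, median -0.17, adjusted p = 0.501). Ribosome biogenesis genes (median 0.43, adjusted p = 0.0975) passed without deleted oil library 1 (adjusted p = 0.0133), granulocyte markers (median 2.70, adjusted p = 0.468) without deleted estradiol library 2 (adjusted p = 0.0475), and mast cell markers (median -1.19, adjusted p = 0.268) without deleted oil library 2 (adjusted p = 0.0365).

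Deletion of Atg7 left no gene past the test in oil (edgeR, 0 of 13347 genes). At an unadjusted p below 0.05 there were 339 genes, where 667 would be expected by chance, and DESeq2 and limma-voom also called 0. The interval of a typical gene reached 0.657 on the log2 scale to each side, and for 58.7% of genes it lay within 2-fold. The genes with the smallest p-values were all higher in deleted stroma. Ak1, adenylate kinase, stood at 3.42 ± 1.93 CPM in control and 11.3 ± 1.20 in deleted stroma. Cela1, an elastase, stood at 3.08 ± 0.103 and 8.76 ± 0.539 CPM, Serpinf1, the secreted factor PEDF, at 9.87 ± 0.567 and 18.0 ± 0.0389, and the selenoprotein gene Selm at 45.8 ± 11.9 and 87.5 ± 16.7. Reads of Dpep1, a membrane dipeptidase, were 8.51-fold higher (95% counting interval 2.04 to 75.7). Each of these genes had an adjusted p of 1. The fibroblast gene Dpt, at 0.72 ± 0.18, passed when adjusted over its list alone, the only list member to do so in oil. A replicate block within each treatment, chosen after seeing the data, gave 1237 genes at an unadjusted p below 0.05 in oil. Of these, 1 passed after adjustment (Plac8). No label says that the replicate numbers pair libraries.

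Gene lists did shift in oil by camera with the preset correlation, in 13 of 33 lists, but no member passed over all genes and every one of these list calls was lost with an estimated correlation (lowest adjusted p = 0.545) and in fry. Medians above 0 belonged to smooth muscle markers (0.49, adjusted p = 3.15e-07), extracellular matrix genes (0.24, adjusted p = 5.52e-07), fibroblast markers (0.38, adjusted p = 1.53e-04), macrophage markers (0.24, adjusted p = 0.00173), cell cycle genes (0.19, adjusted p = 0.00296), progesterone and decidual stroma genes (0.20, adjusted p = 0.00975), erythroid markers (0.32, adjusted p = 0.0274) and pericyte markers (0.33, adjusted p = 0.033). Medians below 0 belonged to epithelium markers (-0.59, adjusted p = 1.35e-06), heat shock genes (-0.30, adjusted p = 3.42e-04), immediate early genes (-0.24, adjusted p = 3.77e-04), epithelial estrogen targets (-0.50, adjusted p = 6.99e-04) and unfolded protein response genes (-0.22, adjusted p = 0.00153). Without control oil library 1, 2 of the 13 calls remained, those of immediate early genes and of macrophage markers (median 0.47), and the medians were 0.28 for epithelium markers (adjusted p = 0.72), 0.11 for heat shock genes (0.853), 0.20 for epithelial estrogen targets (0.644), -0.14 for pericyte markers (0.644) and 0.03 for smooth muscle markers (0.943). The calls of cell cycle genes (median 0.19, adjusted p = 0.464), extracellular matrix genes (0.22, adjusted p = 0.146) and fibroblast markers (0.27, adjusted p = 0.0642) ended there with medians on the same side of 0. For unfolded protein response genes (-0.00, adjusted p = 0.853), progesterone and decidual stroma genes (0.08, adjusted p = 0.644) and erythroid markers (0.05, adjusted p = 0.724) the medians then lay near 0. When deleted oil library 2 was left out instead, 3 of the 13 calls remained, those of cell cycle genes (median 0.11), immediate early genes and smooth muscle markers (median 0.31). The adjusted p was then 0.253 for extracellular matrix genes (median 0.03), 0.442 for epithelium markers (-0.20), 0.0731 for fibroblast markers (0.08), 0.302 for heat shock genes (-0.09), 0.253 for unfolded protein response genes (-0.16), 0.0731 for progesterone and decidual stroma genes (0.13) and 0.906 for pericyte markers (-0.02). Macrophage markers (0.24, adjusted p = 0.0731), epithelial estrogen targets (-0.46, adjusted p = 0.0664) and erythroid markers (0.28, adjusted p = 0.0947) kept medians close to those with all libraries.

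The remaining oil libraries moved the lists further. With control oil library 2 left out, the calls of immediate early genes (-0.25, adjusted p = 0.0528) and macrophage markers (0.11, adjusted p = 0.506) ended. The medians were then 1.06 for smooth muscle markers, 0.38 for extracellular matrix genes, -1.08 for epithelium markers, -0.66 for heat shock genes, -1.07 for epithelial estrogen targets, -0.39 for unfolded protein response genes, 0.30 for cell cycle genes, 0.47 for progesterone and decidual stroma genes, 0.48 for erythroid markers and 0.94 for pericyte markers. With deleted oil library 1 left out, the erythroid call ended (0.21, adjusted p = 0.203), and the medians were -1.10 for epithelium markers, 0.43 for extracellular matrix genes, -0.49 for heat shock genes, -0.77 for epithelial estrogen targets, -0.33 for unfolded protein response genes and 0.61 for pericyte markers. Inflammatory mediators (median 0.01, adjusted p = 0.139) passed without control oil library 2 (median 0.43), deleted oil library 1 (median 0.31) or either control estradiol library (median 0.05), and interferon response genes (0.14, adjusted p = 0.278) without control oil library 2 (0.46) or deleted oil library 1 (0.35). Ribosome biogenesis genes (-0.09, adjusted p = 0.0859) passed without the same pair of libraries (-0.17 and -0.31). Endothelium markers (-0.05, adjusted p = 0.616) passed without control oil library 1 (-0.25), cholesterol synthesis genes (0.04, adjusted p = 0.326) without deleted oil library 2 (0.11) and mast cell markers (-0.01, adjusted p = 0.621) without deleted oil library 1 (-0.75). Lymphocyte and NK markers (0.68, adjusted p = 0.0647) passed without deleted oil library 1 (1.27) or any of the 4 estradiol libraries (0.69 to 0.71). Autophagy core genes (median -0.08, adjusted p = 0.63), autophagy receptors (0.05, adjusted p = 0.477), lysosome genes (0.03, adjusted p = 0.462) and NRF2 targets (-0.02, above 0 with library totals, adjusted p = 0.63) were not called, the last of them passing without control oil library 1 (median 0.34, adjusted p = 0.0186).

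**Figure D4:**
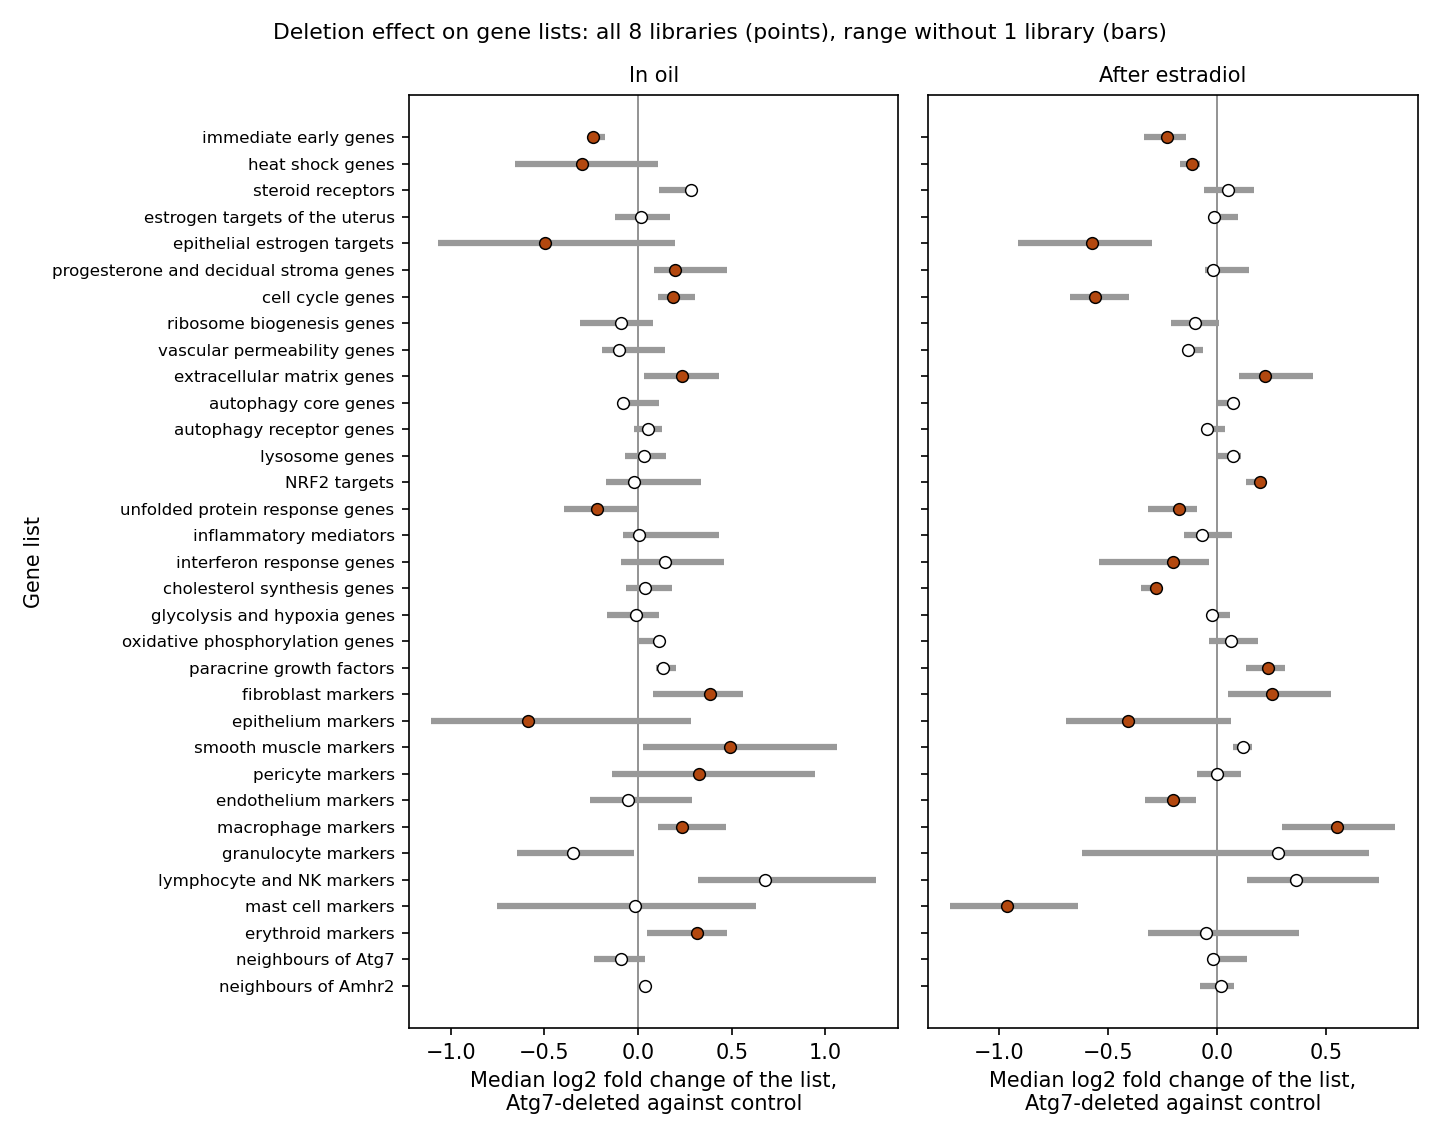
Median log2 fold change of each list, Atg7-deleted against control, in oil (left) and after estradiol (right), with all 8 libraries (points, filled where the camera adjusted p was below 0.05 with the preset correlation) and the range of medians when 1 library was left out (grey bars). In oil the epithelium bar runs from -1.10 to 0.28, across 0, and after estradiol the cell cycle bar runs from -0.68 to -0.40.

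After estradiol, deletion of Atg7 again left no gene past the test (edgeR, 0 of 13347 genes, 403 at an unadjusted p below 0.05, 0 with DESeq2 and 0 with limma-voom). Actc1 (chromosome 2, 114047282 to 114053548, minus strand), cardiac alpha actin, had the smallest p, at 2.44 ± 0.682 CPM in control and 13.1 ± 1.78 in deleted stroma, a log2 fold change of 2.43 ± 0.39. Gstm1, a glutathione transferase, stood at 119 ± 7.22 and 204 ± 5.35 CPM, the axon guidance gene Draxin at 2.11 ± 0.375 and 7.92 ± 0.00679, Dpep1 at 1.40 ± 0.198 and 6.34 ± 0.958, and the complement protease C1ra at 52.1 ± 5.69 and 89.6 ± 1.80. Each of these had an adjusted p of 1. Cell cycle genes had a median log2 fold change of -0.56 (camera adjusted p = 1.35e-18, and adjusted p = 0.195 with an estimated correlation), between -0.68 and -0.40 in the 8 fits without 1 library. Within that list Ube2c, which ubiquitinates mitotic cyclins, stood at 43.9 ± 8.96 CPM in control and 18.9 ± 5.57 in deleted stroma and passed when adjusted over the list alone. Cholesterol synthesis genes had a median of -0.28 (adjusted p = 2.22e-05, and adjusted p = 0.335 with an estimated correlation) and NRF2 targets of 0.20 (adjusted p = 1.01e-04, and adjusted p = 0.381 with an estimated correlation). Both of these kept their calls in all 8 fits without 1 library. Gstm1 and Gsta2, glutathione transferases of the NRF2 list, and Lpl, lipoprotein lipase, of the adipocyte list passed when adjusted over their lists alone. Lpl was named after its value was seen. With a replicate block within each treatment, 21 genes passed after estradiol, with the same limits as in oil.

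For the other 12 lists called after estradiol the adjusted p with an estimated correlation was at least 0.195 each. Above 0 lay macrophage markers (0.55, adjusted p = 1.44e-06), with 0.31 without control estradiol library 2 and no call without deleted estradiol library 1 (0.30, adjusted p = 0.107). Extracellular matrix genes (0.22, adjusted p = 1.8e-05) stood at 0.44 without control estradiol library 1 and lost their call without control estradiol library 2 (0.10, adjusted p = 0.166). Paracrine growth factors (0.23, adjusted p = 0.00173) lost theirs without control estradiol library 2 (0.19, adjusted p = 0.0789) and stood at 0.13 without deleted estradiol library 2. Fibroblast markers (0.25, adjusted p = 0.00324) stood at 0.52 without control estradiol library 1 and lost theirs without control estradiol library 2 (0.05, adjusted p = 0.691) or deleted estradiol library 1 (0.08, adjusted p = 0.276).

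Below 0 lay epithelial estrogen targets (-0.57, adjusted p = 9.97e-06), with -0.30 without control estradiol library 2 and -0.91 without deleted estradiol library 2, and heat shock genes (-0.11, adjusted p = 0.00136), with -0.17 without control estradiol library 1. Mast cell markers (-0.97, adjusted p = 0.00297) lost their call without deleted estradiol library 2 (-0.64, adjusted p = 0.218). Immediate early genes (-0.23, adjusted p = 1.01e-04) lost theirs without control estradiol library 1 (-0.14, adjusted p = 0.0688) and without deleted estradiol library 2 (-0.17, adjusted p = 0.113). Unfolded protein response genes (-0.18, adjusted p = 0.00171) lost theirs without the same libraries (-0.09 and -0.10, adjusted p = 0.392 and 0.218), and stood at -0.30 without control estradiol library 2 and -0.32 without deleted estradiol library 1. Epithelium markers (-0.41, adjusted p = 0.00164) lost theirs without control estradiol library 2, where the median was 0.06 (adjusted p = 0.633), and without deleted estradiol library 1 (-0.20, adjusted p = 0.379), and stood at -0.67 and -0.69 without control estradiol library 1 and deleted estradiol library 2. Interferon response genes (-0.20, adjusted p = 0.00928) lost theirs without control estradiol library 2 (-0.18, adjusted p = 0.166) and deleted estradiol library 1 (-0.04, adjusted p = 0.703), and stood at -0.54 without deleted estradiol library 2. Endothelium markers (-0.20, adjusted p = 0.0199) lost theirs without control estradiol library 1 (-0.19, adjusted p = 0.199) and deleted estradiol library 1 (-0.10, adjusted p = 0.385), and stood at -0.33 without deleted estradiol library 2. Erythroid markers (-0.05, adjusted p = 0.948) passed upward without control estradiol library 1 (0.38, adjusted p = 0.00416) and downward without control estradiol library 2 (-0.32, adjusted p = 0.0497). Granulocyte markers (0.28, adjusted p = 0.624) passed without control estradiol library 1 (0.70) or deleted estradiol library 2 (0.35), lymphocyte and NK markers (0.36, adjusted p = 0.288) without deleted estradiol library 2 (0.74), inflammatory mediators (-0.07, adjusted p = 0.422) without control estradiol library 2 (-0.14) and ribosome biogenesis genes (-0.10, adjusted p = 0.163) without control estradiol library 1 (-0.21). Autophagy core genes (median 0.07, adjusted p = 0.436), lysosome genes (0.07, adjusted p = 0.288) and smooth muscle markers (0.12, adjusted p = 0.304) were not called. Autophagy receptors had a median of -0.04 and a mean of 0.09 (adjusted p = 0.304).

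Averaged over oil and estradiol, with 4 libraries on each side, deletion left no gene past the test in edgeR (543 at an unadjusted p below 0.05, smallest adjusted p = 0.999) or limma-voom, and 3 genes in DESeq2. Those 3, named after their values were seen, were Clec3b, the plasma protein tetranectin (log2 fold change 1.37 in DESeq2 and 1.36 ± 0.25 in edgeR), Saa3, an acute phase protein (1.82 in DESeq2 and 1.81 ± 0.38 in edgeR), and Ak1 (1.31 and 1.31 ± 0.25), each higher in both deleted libraries than in both control libraries within each treatment. For 77.1% of genes the interval of the average effect lay within 2-fold. A replicate block within each treatment, chosen after seeing the data, gave 87 genes in edgeR, with the limit that no label pairs the replicate numbers. Across genes the deletion effects in oil and after estradiol correlated at r = 0.143, and 56.5% of genes had the same sign in both. By camera with the preset correlation 15 lists shifted (10 to 17 without 1 library), while with an estimated correlation (lowest adjusted p = 0.207) and in fry 0 did. Above 0, extracellular matrix genes had a median of 0.30 (adjusted p = 1.08e-09), 0.13 without deleted oil library 2, and macrophage markers of 0.53 (adjusted p = 9.68e-08), 0.34 without control estradiol library 2 and 0.26 without deleted estradiol library 1. Below 0, immediate early genes had a median of -0.25 (adjusted p = 4.73e-07). Epithelium markers had a median of -0.45 (adjusted p = 9.68e-08), which was 0.03 without control oil library 1 (adjusted p = 0.0826), -0.17 without control estradiol library 2, -0.23 without deleted oil library 2, and -0.72 without control oil library 2 or deleted oil library 1. When adjusted over their lists alone, Dpt, Dcn and Mfap5 of the fibroblast list, Aif1 of the macrophage list and Gstm1 of the NRF2 list lay higher, and Hspa1a and Hspa1b of the heat shock list, Lcn2 and Sprr2b of the epithelial estrogen targets and Csf3 of the inflammatory mediators lay lower.

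The difference between the estradiol responses of the genotypes was tested as an interaction. No gene passed (edgeR, 0 of 13347 genes, 210 at an unadjusted p below 0.05, 0 with DESeq2 and 0 with limma-voom). The interval of a typical gene reached 0.928 to each side on the log2 scale, and for 36.5% of genes it lay within 2-fold. Actc1 had an interaction of 3.06 ± 0.62, Paox, a polyamine oxidase, of -2.28 ± 0.47, Cdk1 of -1.58 ± 0.33, Ube2c of -1.91 ± 0.41 and the spindle gene Knstrn of -2.96 ± 0.66, each with an adjusted p of 1. Cell cycle genes had a median interaction of -0.61 and a mean of -0.75, which is a smaller response in Atg7-deleted stroma (adjusted p = 8.08e-18, and adjusted p = 0.447 with an estimated correlation). Their median lay between -0.85 and -0.50 in the 8 fits without 1 library, and the list was called in each. Cdk1, Top2a and Ube2c of this list, and Lyz2 of the macrophage list, passed when adjusted over their lists alone. In the libraries, the mean log2 CPM of cell cycle genes was 2.17 and 2.33 in control oil, 2.46 and 2.49 in deleted oil, 4.50 and 4.58 in control estradiol, and 3.84 and 4.15 in deleted estradiol. In a comparison of 2 of these groups, the smallest exact p that 2 libraries against 2 can give is 0.333. The interaction uses all 4 groups, so that value is not its lower limit.

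Another 4 lists had an interaction with the preset correlation and not with an estimated one (adjusted p = 0.714 for cholesterol synthesis genes and 0.894 for the others). Cholesterol synthesis genes had a median of -0.38 (adjusted p = 8.26e-05), which was -0.22 without control oil library 2 (adjusted p = 0.0846) and -0.26 without deleted oil library 1 (adjusted p = 0.125). Smooth muscle markers had a median of -0.45 (adjusted p = 0.00512), which was 0.12 without control oil library 1 (adjusted p = 0.469), -1.03 without control oil library 2 and -0.18 without deleted oil library 2 (adjusted p = 0.277). Interferon response genes had a median of -0.36 (adjusted p = 0.00704), with -0.06 without control oil library 1 (adjusted p = 0.971), -0.08 without deleted oil library 2 (adjusted p = 0.776), -0.25 without deleted estradiol library 1 (adjusted p = 0.389) and -0.27 without control estradiol library 2 (adjusted p = 0.0799). It was -0.65 without control oil library 2, -0.56 without deleted oil library 1 and -0.64 without deleted estradiol library 2. NRF2 targets had a median of 0.11 (adjusted p = 0.0261), which was -0.05 without control oil library 1 (adjusted p = 0.971), 0.34 without control oil library 2 and 0.33 without deleted oil library 1. Their call also ended without deleted oil library 2 (median 0.18, adjusted p = 0.582), control estradiol library 1 (median 0.12, adjusted p = 0.15) and deleted estradiol library 2 (median 0.07, adjusted p = 0.093). The number of lists called was 11 without control oil library 2, 8 without deleted oil library 1 and 3 without deleted oil library 2.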

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

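The interaction tests were planned, and of the tests of explanations in this part, the comparison with random, equally induced genes had its prediction written before its result was seen while the others were chosen afterwards. The results below stand out because the estradiol effect of a gene list differed between the genotypes by the test of the interaction (camera, preset correlation). The adjusted p was 8.08e-18 for cell cycle genes, 8.26e-05 for cholesterol synthesis genes, 0.00512 for smooth muscle markers, 0.00704 for interferon response genes and 0.0261 for NRF2 targets. With an estimated correlation none of the 33 lists passed for the interaction. Without control oil library 1 the test of smooth muscle markers changed direction (median 0.12), while that of NRF2 targets stayed upward, with a median of -0.05 and an adjusted p of 0.971.

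The smaller estradiol response of cell cycle genes in Atg7-deleted stroma was the steadiest of these, and no library alone carried it, since the median interaction nearest to 0 among the 8 fits without 1 library was -0.50 and the list was called in each. Correlated expression within the list may make the preset test overstate it: the adjusted p was 0.447 with an estimated correlation, a test that gave 0.123 for the estradiol effect of the same list and so cannot decide. Random lists do not settle whether a general shrinking of the estradiol response (slope 0.915, deleted on control, among genes called in either genotype) accounts for the -0.61 of this list: 30 of 1000 matched on the control estradiol effect were as low, but that choice itself lowers their interaction, and of 1000 matched on the average effect 0 were (median -0.17), without allowance for correlated genes. A different mix of cells was not separated either: in deleted against control stroma, epithelium markers stood at -0.59 in oil and -0.41 after estradiol (interaction 0.13), epithelial estrogen targets at -0.50 and -0.57 (-0.09) and macrophage markers at 0.24 and 0.55 (0.03, below 0 with library totals), so their shifts were alike in sign in both treatments where cell cycle genes stood at 0.19 and -0.56, and single libraries moved them as given above. Not all marker lists were alike in both treatments: the deletion medians of smooth muscle and mast cell markers, given above, were lower after estradiol than in oil, as for cell cycle genes. A weaker proliferative response of stroma without Atg7 remains a hypothesis that the libraries (2 per group) cannot separate from these explanations.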

How the results depend on the processing

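All alternatives marked as planned were run except the 3 meant for normalized values (pseudocounts of 0.1 and 5, and no filter on low values), which do not apply to counts. Of the results for named genes, 6365 were counted as the same, 65 as stronger, 157 as weaker and 0 as reversed. For the list tests these counts were 1893, 78, 197 and 10. A change of direction counted as reversed only where the main fit or the alternative passed the threshold. Results counted as the same can therefore include changes of direction without a call. The tally for named genes includes the alternatives chosen after seeing the data. For the estradiol effect in control stroma the count was 2305 with the 2 groups alone in the fit and 2587 with the 2-fold threshold, and 1505 to 4168 when libraries were left out in turn. In Atg7-deleted stroma it was 4257 with the 2 groups alone, against 3242 in the fit of all 8 libraries, 2129 with the 2-fold threshold and 740 to 4345 with libraries left out, and for the average estradiol effect 2971 with that threshold. A 2-fold threshold removes smaller changes by construction; for all other changes the cause was not tested. With 1 library left out, the remaining library of its group is assumed to vary like the other groups. The average deletion effect had 4 genes without the filter on low counts (Ak1, Sprr2b, Saa3 and Clec3b), 3 with DESeq2 and 0 to 1 with libraries left out (Sprr2b, without control oil library 2). The replicate number as a replicate block gave 4094 and 3423 genes for estradiol in control and Atg7-deleted stroma, 6227 for the average and 0 for deletion and interaction. Differences between the libraries numbered 1 and 2 correlated at 0.494 between genotypes in oil and 0.230 after estradiol, but no label says that a number marks a shared animal, litter or day. A crossed pairing, chosen after seeing the data like the next alternatives, gave 4946 and 4324. A replicate block within each treatment gave 1 gene for deletion in oil (Plac8), 21 after estradiol and 87 for the average, and leaving out Rn45s gave 3978 and 3239 for estradiol. List calls fell to 0 with an estimated correlation for estradiol in either genotype, for deletion in oil, after estradiol and on average, and for the interaction, and fry called 0 for deletion in oil, after estradiol, on average and for the interaction, but 8 and 9 for estradiol in control and Atg7-deleted stroma. With libraries left out in turn, 4 to 17 lists were called for deletion in oil and 3 to 11 for the interaction. List tests whose direction reversed, each with its adjusted p and the range over libraries left out, were, for deletion in oil without control oil library 1, heat shock genes (0.853; 1.89e-07 to 0.853), epithelial estrogen targets (0.644; 1.1e-08 to 0.644), epithelium markers (0.72; 5.25e-12 to 0.72), smooth muscle markers (0.943; 2.71e-25 to 0.943), and pericyte markers (0.644; 5.65e-05 to 0.906). After estradiol, erythroid markers reversed without control estradiol library 2 (0.0497, range 0.00416 to 0.991). In the interaction, heat shock genes (0.0468, range 0.0107 to 0.928), epithelium markers (0.0182, range 1.33e-04 to 0.707) and smooth muscle markers (0.469, range 1.92e-18 to 0.469) reversed without control oil library 1, and epithelial estrogen targets without control oil library 2 (0.0224, range 7.21e-04 to 0.776). At this depth and number of libraries, 21 of 100 2-fold changes were called for deletion in oil in simulated data with independently drawn genes. Atg7 and Amhr2 had too few reads for a precise fold.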

Other observations

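The test on all splits for the average estradiol effect was planned and predicted before its result was seen; the other tests in this part were chosen afterwards. Among the 35 splits of the 8 libraries into 4 and 4, 1 gave as many genes as the real estradiol split, the real split itself. It gave 6628 genes in a fit of 2 groups against 0 for the highest other. That share was under the planned limit, but it is also the smallest that 35 splits can give. Every other split mixes oil and estradiol libraries on both sides, which widens the error of its fit. The splits alone therefore do not exclude chance. The estradiol calls of the 2 genotypes, which share no library, argue against it for the genes called in both. As given above, 1459 genes rose and 1240 fell in both, where independent calls would share 276 and 210. No gene was called in opposite directions. For the average deletion effect the real split gave 0 genes, a count that 35 of 35 splits reach whatever the data, so the splits decide nothing there. The highest other, at 6628, was the split by estradiol.

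Epithelium markers were lower after estradiol, though the libraries are labelled as stroma, and Cldn4 and Krt18 were abundant in oil. A lower share of epithelial cells would lower the markers alike only if no other cells in the libraries expressed them. Their average estradiol effects spread far more widely than their errors (Cochran's Q, chi-square p = 1.09e-40 over 22 markers, weighted mean -1.08), with the limit that markers measured in the same libraries share errors. Expression of the markers in other cells was not measured, so the spread cannot decide whether that share was the whole cause. Epithelial estrogen targets moved the other way, with medians of 2.70 in control and 2.48 in Atg7-deleted stroma. They are other genes, and which cells expressed them was not measured, so their rise cannot decide it either. Control oil library 1 did not carry the pattern alone, since the median in control stroma without it was -0.81. A lower share, as part or the whole of the cause, and regulation of these genes by estradiol may contribute, and neither was separated.

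Epithelium markers also lay lower in Atg7-deleted stroma, with list means (log2 CPM) per library of 7.42 and 6.30 in control against 6.81 and 5.89 in deleted stroma in oil, and 5.13 and 5.71 against 4.78 and 5.33 after estradiol, so the libraries of the genotypes overlapped. Each deleted library lay below the control library with the same treatment and replicate number, but no label says that the numbers pair libraries. The call and the sign changed with single libraries: the median was 0.28 in oil and 0.03 on average (adjusted p = 0.0826) without control oil library 1, and 0.06 after estradiol without control estradiol library 2 (adjusted p = 0.633). With an estimated correlation the adjusted p of the average was 0.45. The average deletion effects of the markers were no more spread than their errors (Cochran's Q, chi-square p = 0.974). These errors include differences between libraries that the markers share, which do not add to the spread between markers. A small spread can therefore arise whatever the cause, and the test cannot decide. A lower share of epithelial cells in some of the Atg7-deleted libraries, or a higher share in some control libraries, may account for the values. That reading is a hypothesis from the same data, and an effect of deletion on the epithelium was not tested separately.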
